A study of Limosilactobacillus reuteri subsp. rodentium with 8 samples.

How the data were processed

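The series held 8 dual-colour arrays, each with the luxS mutant and the wild type of strain 100-23 in the same growth condition. Per the labels' protocols, cultures were grown anaerobically at 37 °C in MRS broth at full strength or diluted to 1 part in 5, and 2 µg of total RNA of each strain was labelled with Cy5 or Cy3 during cDNA synthesis. The mutant carried Cy5 and Cy3 once each in log phase and in stationary phase, and Cy3 on 3 arrays and Cy5 on 1 in dilute medium. The series' design text describes the arrays as independent biological replicates. Per the file headers, the arrays lay on 2 slides of 4 arrays, slide 1 with log phase and stationary phase and slide 2 with dilute medium, and each slide had 1 scan. How the mutant was made is not given in the sources used here.

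Per the file headers and the submitters' processing notes, spots were quantified with Agilent Feature Extraction 9.5.3.1. The deposited scanner files give each spot's mean intensity and the median intensity of its local background in both dyes, with no normalization, as well as processed signals from which the software had removed the background and balanced the dyes. They also give the log10 ratio of processed Cy5 to processed Cy3, and marks for saturated spots, for outlier spots and for spots well above background. The deposited value table of the series was set against these ratios: its log10 ratios correlated with those of each array at 1 or -1, with the sign turned where the mutant carried Cy3, so its values are log10 of mutant over wild type in the scale of the scanner software, with no further centring. Column medians lay between -0.00228 and 0.00913, and 2.24% to 5.34% of the values per array were exactly 0.

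The ratios used here were computed from the unprocessed intensities with limma 3.58.1 in R 4.3.3. Background was corrected with normexp at an offset of 50, and each array was normalized with loess, in which 1417 control spots, 189 spike spots and outlier spots had weight 0. Spots marked as non-uniform or as population outliers in either dye were left out, and saturated spots were kept. Log2 ratios were turned to mutant over wild type by the dyes in the labels, spots of a probe name were averaged, and a locus took the mean of its probe names, of which there were a median of 7. Loci with at least 2 usable arrays in each condition were tested, 2375 of 2377. The array's identifiers name 2143 loci by a locus tag and 234 by a number alone. Of 18316 identifiers searched, 0 matched the gene table that was given, which belongs to another strain. For this reason the 23 gene lists fixed beforehand could not be tested with camera, with a preset or an estimated correlation, and the luxS transcript could not be singled out. The 7494 distinct probe sequences were also translated in the forward frames and searched for the motif His-x-x-Glu-His, which LuxS proteins carry, after the data had been examined. The marker genes ErmC, CmR and Tet are named on the array and are left out of all counts of loci.

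A linear model was fitted across all loci with lmFit and eBayes, with 1 coefficient for each growth condition and the dye orientation as a covariate, over all 8 arrays, so that conditions with 2 arrays share the spread of all. It left 4 residual degrees of freedom, with a prior of 3.45. The mutant effect in each condition, its unweighted mean over the 3 conditions and the differences between conditions were tested, with Benjamini-Hochberg adjustment over the loci of each test and a threshold of 0.05. Every adjusted p in the text comes from limma. The design, the alternatives and the rule for named loci were fixed before the data were examined. The rule took the loci with the largest positive and negative ratios among those past the threshold with the same sign on every array of the condition, and the smallest p where fewer than 5 passed. For a difference between conditions it was read, later on, as asking that no array of one condition overlap with those of the other. As the files give no names, at most 2 raised and 2 lowered loci are given for each comparison.

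For the comparison of growth conditions in the wild type, the log2 signals of the wild-type channel were taken after loess and Aquantile normalization and fitted with the condition and the dye of the wild type. Only the 8809 probe names with a usable spot on all 8 arrays entered, which left 2092 loci. The quantile step ran over all gene spots, outlier spots included, which were then left out. This order was settled after the data had been examined, since bright spots on slide 2 were marked as outliers more often, and leaving them out first moved the levels of the dilute-medium arrays. A lower bound on a fold change was given where a marker or locus was well above background in one strain on none of the arrays of a condition.

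The fits were tested on simulated ratios with each locus's residual spread, missing values and dye effects. In these, 200 loci were changed by a log2 size of 0.5, 1 or 2. The noise was drawn independently and with the same spread on all arrays, while weights estimated for the real arrays ran from 0.258 to 2.11. The shares recovered and the false calls may therefore differ in the real data. With a change of 1, the share recovered among 2375 loci was 83.6% for log phase, 88.1% for stationary phase, 95.5% for dilute medium, 92.5% for the mean of the conditions, 61.2% for the difference of stationary phase and log phase, 76.1% for dilute medium and log phase, and 77.6% for dilute medium and stationary phase. Among the unchanged loci the false calls were 15, 7, 12, 10, 7, 3 and 6 in the same order, which in several of these tests, most of all in log phase, was above the share of calls that the threshold allows for. At a change of 0.5, log phase and stationary phase recovered 38.8% and 37.3%, and dilute medium 71.6%. For the wild-type levels, over 2092 loci, a change of 1 was recovered in 35.8% of cases from log phase to stationary phase and 58.2% from log phase to dilute medium, with 4 and 7 false calls, the latter again above that share.

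The alternatives were no background correction, the processed signals of the scanner software without loess, median centring, a filter on dim probes, scaling between arrays, the median over probes, no dye covariate, fits of 1 condition alone, leaving out each array in turn, the replicate number as a block, array weights and the deposited value table. For the wild-type levels they were quantile normalization, the mutant channels, no dye covariate, the replicate block and a filter on dim probes. A slide term could not be fitted beside the conditions, because slide 2 held dilute medium alone, and fits within each slide were added after the data had been examined, as were fits with outlier spots kept and with loci measured on all arrays only.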

Results

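Transcript levels of a luxS mutant of *Limosilactobacillus reuteri* 100-23, a bacterium of the rodent gut, were compared with those of its wild type on dual-colour oligonucleotide arrays. LuxS is an enzyme of the activated methyl cycle, and its reaction also releases the precursor of a quorum sensing signal, so its loss can act through metabolism or through signalling, which is the question the study posed. Each of the 8 arrays carried cDNA of the mutant in one dye and of the wild type in the other, from cultures of the same growth condition. There were 2 arrays for log phase in full-strength MRS broth, 2 for stationary phase in the same broth, and 4 for cultures in MRS diluted to 1 part in 5. According to the labels, RNA was taken after 4 h, after 8 h, or when a dilute culture reached an optical density of 0.4.

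The arrays held 45220 spots each, of which 43614 lay on 2377 chromosomal loci and 3 resistance markers, with a median of 19 spots and 3 distinct probe sequences of 60 bases per locus. Between 87.7% and 96.5% of these spots were well above background in the mutant channel, and between 90.7% and 96.4% in the wild-type channel. Spots with an outlier flag made up 3.74% to 4.48% on the log-phase and stationary-phase arrays. On the dilute-medium arrays they made up 32.7%, 40.1%, 21.2% and 52.4% for replicates 1 to 4, and 192 loci had no usable spot on replicate 4. The precision is limited by the number of arrays. The files name the loci by locus tags or numbers and do not pair them with gene names, so the named loci are given by tag and the targeted gene, for which a motif in the probes gives only a candidate, can be one of them.

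The resistance marker ErmC, a methyltransferase gene that gives resistance to erythromycin, was far higher in the channel labelled mutant on all 8 arrays, with log2 ratios of mutant to wild type from 6.90 to 9.13. Its ratio was 7.75 ± 0.28 (log2, SE, n = 2) in log phase, 7.38 ± 0.28 (n = 2) in stationary phase and 8.48 ± 0.21 (n = 4) in dilute medium, with adjusted p of 2.17e-05, 3.13e-05 and 1.4e-06. In log phase and stationary phase the wild-type signal of ErmC was not well above background. Lower bounds of 215-fold and 159-fold were therefore taken for the mean ratio. They make no allowance for the spread of the arrays, and stationary phase replicate 1 stood at 6.90 (log2), below its bound of 7.316. These bounds set the mean normalized mutant level against the higher of the wild-type signal and the lowest signal well above background on each array, and with the dyes balanced in both conditions they are not tied to 1 dye. In dilute medium ErmC was above background in the wild-type channel of 1 of the 4 arrays, and 30.6% of its mutant spots were saturated. The other markers, CmR for chloramphenicol and Tet for tetracycline, did not pass the test in any condition, with ratios of 0.10 ± 0.09 (log2, SE) for CmR and 0.12 ± 0.09 for Tet in dilute medium (adjusted p of 0.611 and 0.561). Both were well above background in neither strain in log phase and stationary phase, and on 1 of the 4 arrays in dilute medium. Their ratios near 0 are therefore largely those of background. ErmC thus lay on the same side for every array and both dye orientations, so the strain labels and the turned ratios agree across the arrays. The sources used here do not say that the mutant carries ErmC. A swap of the strains on all arrays would therefore not show in this check.

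**Figure D1:**
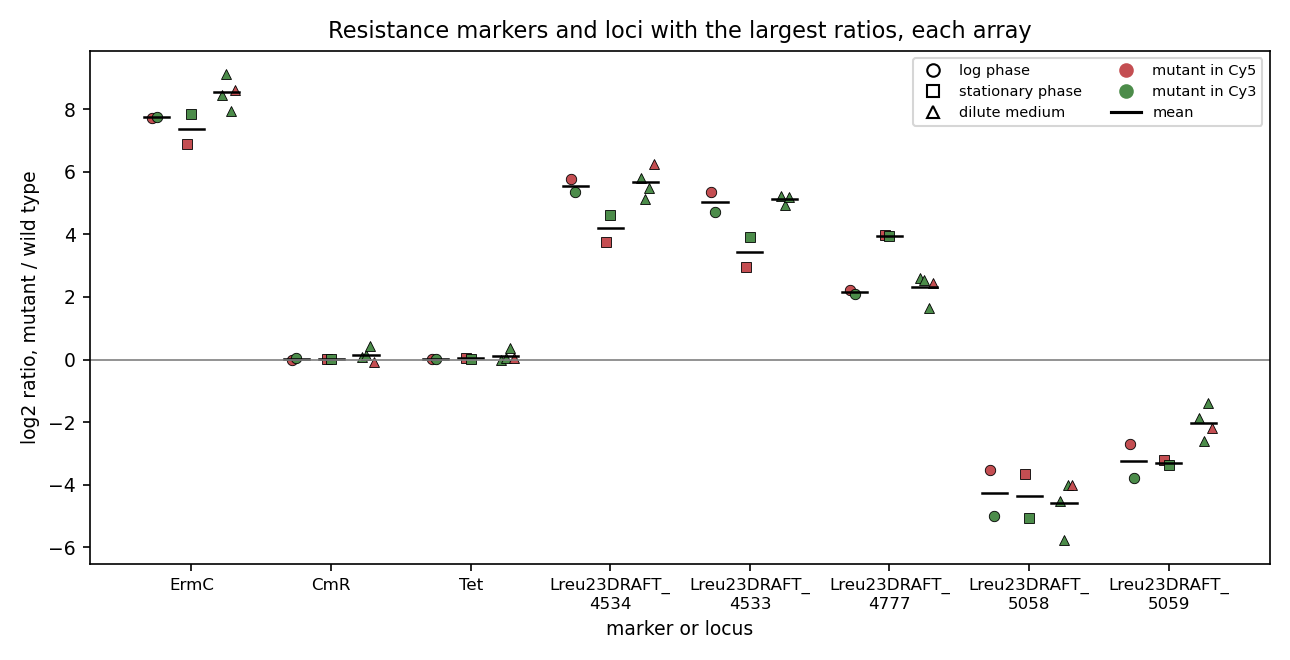
Each point is the log2 ratio of mutant to wild type (vertical axis) of one array for 3 resistance markers and 5 loci (horizontal axis), with growth condition as the symbol, the dye of the mutant as the colour and a bar at the mean of the arrays of a condition. ErmC lies between 6.90 and 9.13 on all 8 arrays, while CmR and Tet stay near 0 except on dilute-medium replicate 3, where they reach 0.42 and 0.38.

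In log phase, Lreu23DRAFT_4534 and its neighbour Lreu23DRAFT_4533 were the most strongly raised loci of the mutant, at 5.55 ± 0.28 (log2, SE, n = 2) and 5.03 ± 0.25, or 46.8-fold and 32.6-fold, with adjusted p of 0.00013 and 0.000258. For Lreu23DRAFT_4534 the probe with the sequence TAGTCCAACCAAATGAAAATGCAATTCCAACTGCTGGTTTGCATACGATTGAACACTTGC gave a mean ratio of 6.87 in this condition. The loci with the largest fall were Lreu23DRAFT_5058 and its neighbour Lreu23DRAFT_5059, at -4.26 ± 0.36 and -3.24 ± 0.30 (adjusted p of 0.000908 and 0.0014). This is 19.2-fold lower for Lreu23DRAFT_5058, while the mutant signal of Lreu23DRAFT_5059 was well above background on 1 of the 2 arrays. In all, 60 of 2375 loci passed the test in limma at an adjusted p under 0.05, 38 of them higher and 22 lower in the mutant, and 18 and 15 of these changed at least 2-fold. All 60 had the same sign on both log-phase arrays, and all were well above background in both strains on at least 1 of them. The balance of higher and lower loci depended on the processing: it was 27 and 7 with median centring, 82 and 115 with scaling between arrays, 77 and 143 with the log-phase arrays alone and no dye covariate, and 234 and 268 with array weights. The count was 14 without log phase replicate 1 and 7 without log phase replicate 2, where the single array left was assumed to vary like those of the other conditions, and 28 without either stationary-phase replicate, 26 without dilute medium replicate 4 and 111 without dilute medium replicate 1. Without log phase replicate 2, Lreu23DRAFT_5058 and Lreu23DRAFT_5059 no longer passed (adjusted p of 0.0873 and 0.088, the highest of all alternatives, with lowest values of 1.54e-07 and 8.68e-06). A fit within slide 1, which held the log-phase and stationary-phase arrays, called 409 loci, 182 higher and 227 lower.

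In stationary phase the mutant again had more transcript of Lreu23DRAFT_4534, by 4.19 ± 0.28 (log2, SE, n = 2; adjusted p = 0.000335), and next to it in size stood Lreu23DRAFT_4777 at 3.95 ± 0.22 (adjusted p = 8.99e-05), which corresponds to 15.5-fold. Lreu23DRAFT_5058 and Lreu23DRAFT_5059 fell again, at -4.36 ± 0.36 and -3.29 ± 0.30 (adjusted p of 0.000883 and 0.00126). In the fit of all arrays, 93 loci passed in limma, of which 21 were higher and 72 lower, and 16 of the former and 50 of the latter changed at least 2-fold. All 93 had the same sign on both stationary-phase arrays. The balance turned without stationary phase replicate 1, to 10 higher and 6 lower of 16 loci, without stationary phase replicate 2, to 7 higher and 0 lower, and with the stationary-phase arrays alone and no dye covariate, to 14 higher and 4 lower. The count was 53 without either log-phase replicate, 61 without dilute medium replicate 4, and 317 in the fit within slide 1 (100 higher, 217 lower). Lreu23DRAFT_5059 did not pass without stationary phase replicate 1 or 2 (adjusted p of 0.0582 and 0.0761), nor did Lreu23DRAFT_5058 without replicate 2 (0.0701). Over all alternatives the adjusted p of Lreu23DRAFT_5058 ran from 1.5e-07 to 0.0701 and that of Lreu23DRAFT_5059 from 1.04e-05 to 0.0761.

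In dilute medium the pair Lreu23DRAFT_4534 and Lreu23DRAFT_4533 stood at 5.72 ± 0.21 (log2, SE, n = 4) and 5.04 ± 0.27 (n = 3), with adjusted p of 9.91e-06 and 9.24e-05, and 39.5% and 5.26% of their mutant spots were saturated. Lreu23DRAFT_5058 fell by 4.29 on the log2 scale (SE 0.27, n = 4; adjusted p = 8.33e-05). Lreu23DRAFT_5044 fell by 2.48 (SE 0.20, n = 4; adjusted p = 0.000309), or 5.58-fold, and was measured by 15 distinct probe sequences. In the fit of all arrays, 130 loci passed in limma, 100 of them higher and 30 lower, and 26 and 9 of these changed at least 2-fold. All 130 had the same sign on every dilute-medium array that measured them, and 2 of the 130 were not well above background in the wild type on any of them. The dilute-medium arrays filled slide 2 alone, so slide and medium cannot be told apart for this condition. The count was 42 without dilute medium replicate 4, 196 without dilute medium replicate 1, 69 without either log-phase replicate and, with the dilute-medium arrays alone, 41 with the dye covariate and 94 without it (71 higher, 23 lower).

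Averaged over the 3 conditions with equal weight, Lreu23DRAFT_4534 and Lreu23DRAFT_4533 were higher by 5.15 ± 0.15 (log2, SE, 8 arrays) and 4.50 ± 0.15 (7 arrays), and Lreu23DRAFT_5058 and Lreu23DRAFT_5059 lower, at -4.31 ± 0.19 and -2.83 ± 0.16 (adjusted p from 2.22e-06 to 3.06e-05). Both raised values include the dilute-medium arrays, where 39.5% of the mutant spots of Lreu23DRAFT_4534 and 5.26% of those of Lreu23DRAFT_4533 were saturated, so their ratios there are capped in part. A total of 280 loci passed in limma, 123 higher and 157 lower, and 19 and 10 of these changed at least 2-fold. Of the 280, 155 had the same sign on all the arrays that measured them. The median ratio of all loci was 0.007 (log2). The count was 69 without log phase replicate 1 (38 higher, 31 lower), 151 without log phase replicate 2, 143 and 115 without stationary phase replicates 1 and 2 (58 higher and 57 lower for the latter), and 164 without dilute medium replicate 4.

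**Figure D2:**
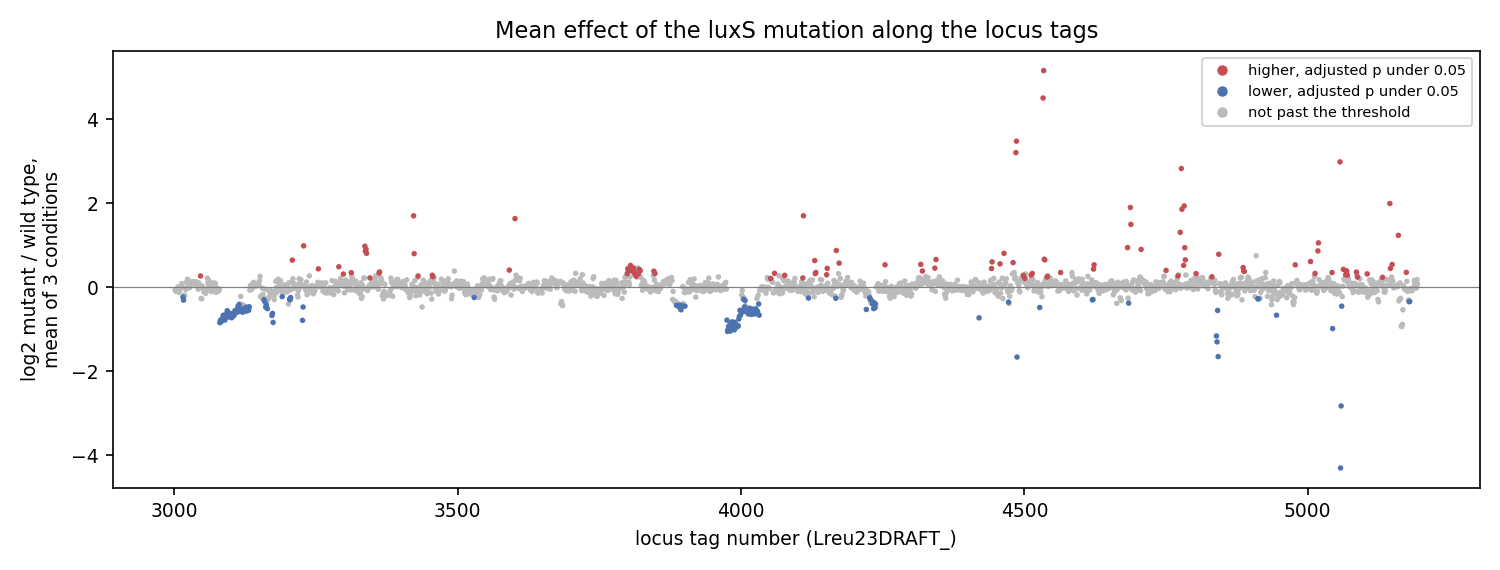
Each point is a locus placed by its tag number (horizontal axis), with its log2 ratio of mutant to wild type averaged over the 3 conditions (vertical axis), coloured where the adjusted p was under 0.05. The 123 raised loci are mostly scattered, with Lreu23DRAFT_4534 and Lreu23DRAFT_4533 highest at 5.15 and 4.50, while many of the 157 lowered loci lie in dense stretches of neighbouring tags at small negative ratios.

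The effects of the mutation were compared between conditions. Across loci, which are not independent replicates, the ratios correlated with r = 0.741 between log phase and stationary phase, 0.696 between log phase and dilute medium, and 0.564 between stationary phase and dilute medium. Without the pair Lreu23DRAFT_4533 and Lreu23DRAFT_4534 these values were 0.712, 0.639 and 0.51. Log phase and stationary phase lay on slide 1 and dilute medium on slide 2. Single arrays of different conditions correlated at a median of 0.643 within a slide and 0.48 across slides. For arrays of the same condition, always on 1 slide, the median was 0.57. The order of r between conditions may thus reflect slide as well as condition, which cannot be told apart. Log phase and stationary phase shared 19 raised loci where independent lists of their sizes would share 0.336, and 20 lowered loci against 0.667. Log phase and dilute medium shared 31 raised loci against 1.6 and 7 lowered loci against 0.278, and stationary phase and dilute medium shared 18 against 0.884 and 5 against 0.909. No locus passed in opposite directions in any of these pairs. In all 3 conditions 18 loci were raised and 5 were lowered, while 77 passed as raised and 75 as lowered in 1 condition only, a count that does not show a difference between conditions. No wild-type array was shared, since each array carried its own wild-type RNA. However, the 3 lists came from 1 fit with 1 spread for each locus, so some sharing can arise without shared effects. The deviations of same-numbered log-phase and stationary-phase arrays also correlated, at 0.489. The figures for independent lists are therefore no test of shared effects.

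**Figure D3:**
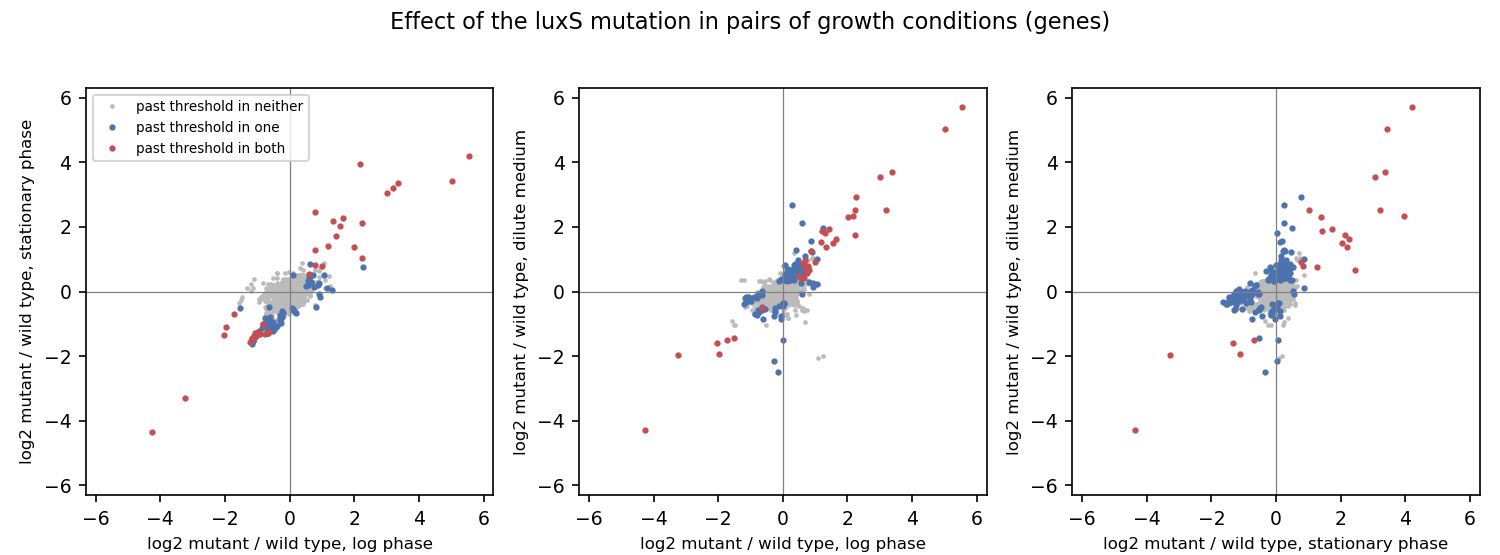
Each point is a locus, with its log2 ratio of mutant to wild type in one growth condition on the horizontal axis and in another on the vertical axis, for the 3 pairs of conditions; colours mark an adjusted p under 0.05 in neither, one or both. The loci past the threshold in both conditions fall in the same quadrants, and r across loci is 0.741, 0.696 and 0.564 from left to right.

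Whether an effect differed between conditions was tested as a difference of effects in the same model. Between stationary phase and log phase no locus passed in limma (158 had an unadjusted p under 0.05), and 1 locus did once dilute medium replicate 3 was left out. The loci with the smallest p were Lreu23DRAFT_4775, whose ratio was 0.80 ± 0.13 (log2, SE) in log phase and 2.45 ± 0.13 in stationary phase (difference 1.65 ± 0.18, adjusted p = 0.0646), and Lreu23DRAFT_5019, at 1.30 ± 0.12 and 0.04 ± 0.12 (difference -1.26 ± 0.17, adjusted p = 0.0918). Lreu23DRAFT_3811 went from 0.92 ± 0.10 in log phase to -0.08 ± 0.10 in stationary phase (adjusted p = 0.0918), and Lreu23DRAFT_4840 had a difference of 1.03 ± 0.16 (adjusted p = 0.118). All 4 of these differences passed in the fit within slide 1, with adjusted p from 0.00496 to 0.0185. That fit, with fewer arrays, called 87 loci, and the fit with array weights called 50. The weights were 1.46 to 2.11 for the arrays of slide 1 and 0.258 to 0.971 for those of dilute medium. The shared spread of the main fit thus took in arrays that were given less weight. Its lack of calls does not show that the effects were alike. Over all alternatives the adjusted p of Lreu23DRAFT_4775 ran from 0.00309 to 0.607, and those of the other 3 loci from 0.00319 to 0.899.

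Between dilute medium and log phase 2 loci passed, both next to each other on the tag list. Lreu23DRAFT_3228 was 2.11 ± 0.09 (log2, SE, n = 4) higher in the mutant in dilute medium and 0.59 ± 0.12 (n = 2) in log phase (difference 1.52 ± 0.15, adjusted p = 0.0158). Lreu23DRAFT_3227 stood at -1.49 ± 0.08 and -0.01 ± 0.11 (difference -1.48 ± 0.13, adjusted p = 0.0148). The next locus by p in each direction did not pass. The differences were 0.87 ± 0.15 for Lreu23DRAFT_4344 (adjusted p = 0.347) and -1.86 ± 0.26 for Lreu23DRAFT_3226 (adjusted p = 0.0978). No locus passed when any one of log phase replicates 1 and 2, stationary phase replicates 1 and 2 and dilute medium replicate 4 was left out (adjusted p of both loci from 0.0752 to 0.572), and 6 and 4 passed without dilute medium replicates 2 and 3. With the scanner software's own signals neither locus passed (adjusted p of 0.149 for Lreu23DRAFT_3227 and 0.297 for Lreu23DRAFT_3228), although their differences were -2.16 and 1.83. Lreu23DRAFT_3228 also failed to pass with scaling between arrays (0.0968) or without the dye covariate (0.187). Over all alternatives the adjusted p of Lreu23DRAFT_3227 and of Lreu23DRAFT_3228 ran from 0.00135 to 0.572, that of Lreu23DRAFT_3226, which passed in 7 of 21 alternatives, from 0.000645 to 0.999, and that of Lreu23DRAFT_4344 from 0.0359 to 0.999. Median centring gave 1 locus with a higher and 3 with a lower ratio in dilute medium, and scaling between arrays 0 and 1.

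Between dilute medium and stationary phase 33 loci passed in limma, 25 with a higher and 8 with a lower ratio in dilute medium (7 and 5 with median centring, 4 and 3 with the scanner software's own signals). Lreu23DRAFT_5145 was raised by 2.93 ± 0.14 (log2, SE, n = 4) in dilute medium and stood at 0.76 ± 0.19 (n = 2) in stationary phase, a difference of 2.17 ± 0.23 (adjusted p = 0.00821). Lreu23DRAFT_3228 followed with 1.86 ± 0.15 (adjusted p = 0.00348). Lreu23DRAFT_3226 and Lreu23DRAFT_5044 had the largest negative differences, -2.18 ± 0.26 and -2.15 ± 0.33 (adjusted p of 0.0125 and 0.038). These 4 calls ended without stationary phase replicate 1 or 2 (adjusted p from 0.0751 to 0.427), where the count was 0. The count was 14 without dilute medium replicate 1 or 3, 6 without replicate 4 and 10 without either log-phase replicate, the call of Lreu23DRAFT_3226 also ended without dilute medium replicate 4 (adjusted p = 0.102), and that of Lreu23DRAFT_5044 without dilute medium replicate 1 or 4 or a log-phase replicate (0.0521, 0.201 and 0.108). With the scanner software's own signals the calls of Lreu23DRAFT_3228 and Lreu23DRAFT_5044 ended (adjusted p of 0.0531 and 0.094), and without background correction that of Lreu23DRAFT_5044 (0.0526). Over all alternatives the adjusted p ran from 0.00097 to 0.115 for Lreu23DRAFT_5145, from 0.000609 to 0.115 for Lreu23DRAFT_3228, from 0.000201 to 0.308 for Lreu23DRAFT_3226 and from 0.000218 to 0.427 for Lreu23DRAFT_5044. Slide and medium changed together in both comparisons with dilute medium.

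**Figure D4:**
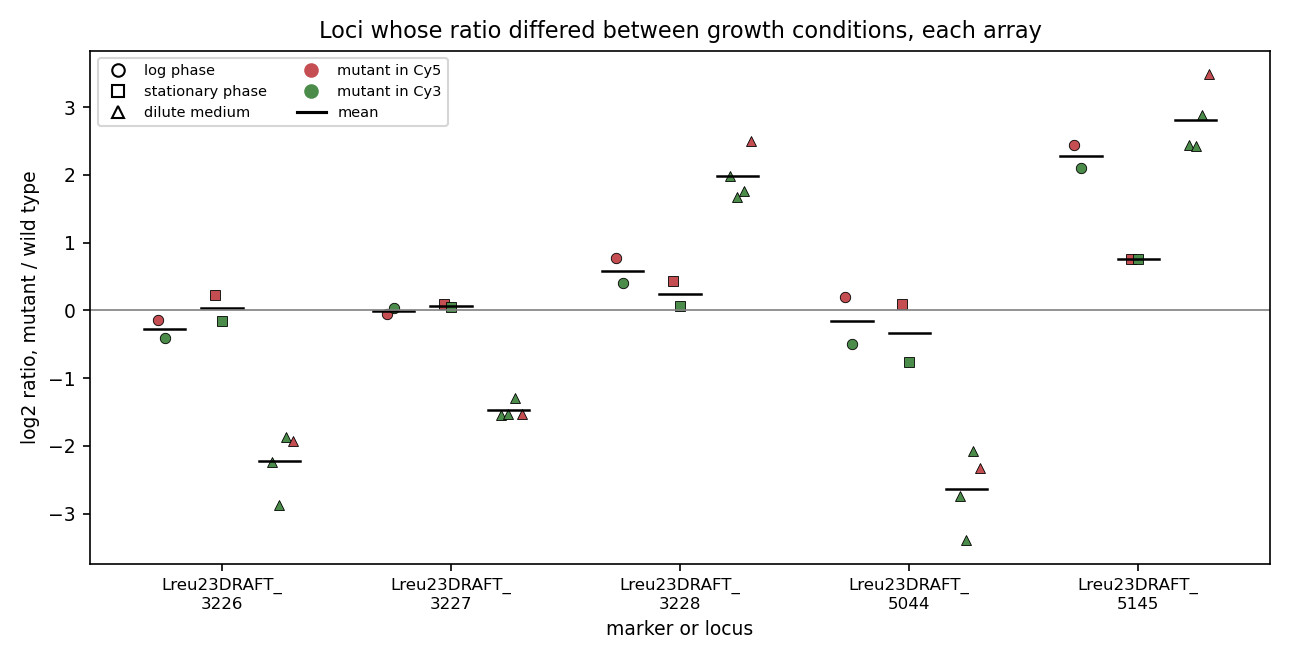
Each point is the log2 ratio of mutant to wild type (vertical axis) of one array for 5 loci (horizontal axis), with growth condition as the symbol, the dye of the mutant as the colour and a bar at the mean of the arrays of a condition. In dilute medium Lreu23DRAFT_3226 and Lreu23DRAFT_3227 lie below -1.2 and Lreu23DRAFT_3228 above 1.6 on all 4 arrays, while in log phase and stationary phase the 3 loci lie between -0.41 and 0.78.

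The wild-type channels were also compared between growth conditions, across arrays. From log phase to stationary phase Lreu23DRAFT_4464 rose by 7.30 ± 0.34 (log2, SE) and Lreu23DRAFT_4514 by 7.19 ± 0.20 (adjusted p of 1.5e-06 and 6.4e-08), and Lreu23DRAFT_3462 and Lreu23DRAFT_3460 fell, at -4.32 ± 0.26 and -4.31 ± 0.28 (adjusted p of 6.37e-06 and 1.04e-05). In all, 886 of 2092 loci passed in limma, 443 higher and 443 lower, and 314 and 272 of these changed at least 2-fold. Both conditions lay on slide 1. The count was 571 without log phase replicate 1.

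From log phase in full-strength medium to dilute medium the wild type had 574 loci past the threshold, 361 higher and 213 lower. With outlier spots kept, an alternative chosen after the data had been seen that also let in more probes and loci (2377 tested), 787 passed, 378 higher and 409 lower. Lreu23DRAFT_4527 and Lreu23DRAFT_4528 had the largest rises, 3.58 ± 0.22 and 3.32 ± 0.43 (log2, SE; adjusted p of 0.000105 and 0.00152). Lreu23DRAFT_4037 and Lreu23DRAFT_5167 had the largest falls, -2.77 ± 0.33 and -2.71 ± 0.71 (adjusted p of 0.0011 and 0.0238). This comparison also crossed slides, so medium and slide cannot be told apart in it. The count was 275 without log phase replicate 1 and 69 without log phase replicate 2. Lreu23DRAFT_5167 did not pass without log phase replicate 1 or 2 or dilute medium replicate 3 (adjusted p of 0.153, 0.141 and 0.0668), nor Lreu23DRAFT_4528 without log phase replicate 2 (0.057). Over all alternatives the adjusted p ran from 0.00174 to 0.208 for Lreu23DRAFT_5167 and from 0.000129 to 0.057 for Lreu23DRAFT_4528.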

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

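The tests of Lreu23DRAFT_3226, Lreu23DRAFT_3227 and Lreu23DRAFT_3228, of Lreu23DRAFT_4533 and Lreu23DRAFT_4534 (the motif search included) and of the shares of raised loci were chosen only after the result was seen, except that for sequence shared with ErmC. The splits of the arrays were planned. The tags on either side of these loci are named because their values were seen.

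The effect of the mutation differed between dilute medium and log phase for 2 loci, Lreu23DRAFT_3228 (difference 1.52, log2) and Lreu23DRAFT_3227 (-1.48), by the test of the difference itself. Between dilute medium and stationary phase it differed for 33 loci, among them Lreu23DRAFT_5145 (2.17), Lreu23DRAFT_3228 (1.86), Lreu23DRAFT_3226 (-2.18) and Lreu23DRAFT_5044 (-2.15).

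Of these, Lreu23DRAFT_3226 to Lreu23DRAFT_3228 are neighbours by tag whose ratios went opposite ways in dilute medium, while the tags on either side, Lreu23DRAFT_3225 and Lreu23DRAFT_3229, stood at -0.07 and 0.01 (log2). Outlier spots do not account for it: with them kept, the smallest of the 6 differences of the 3 loci was 1.47 in size. Nor does a single array, since the smallest difference without any one of the dilute-medium arrays was 1.41. Slide and scan remain open, because 0 slides held both dilute-medium and other arrays, so that slide and medium cannot be told apart for these loci. An effect of the medium on the mutant, which the design names, may also be the source and was not tested apart from the slide.

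Lreu23DRAFT_4533 and Lreu23DRAFT_4534 were raised on every array that measured them, as was the marker ErmC. A single misleading probe is argued against by the lowest mean ratio among their distinct sequences, 4.49 (log2), and sequence shared with the ErmC probes by a longest common stretch of 8 bases. A candidate explanation is transcription that starts at an inserted marker and runs into the pair: within 3 tags of the pair the highest mean ratio was 0.66, at Lreu23DRAFT_4535, and it was also raised at Lreu23DRAFT_4536. The pair may hold the targeted gene itself, since a probe of Lreu23DRAFT_4534 reads His-x-x-Glu-His, a motif of LuxS proteins, but so do probes of 6 of the other loci, and neither the name of the locus nor the marker's place is known here. This stays open, as does an effect of the loss of LuxS.

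Raised loci made up 76.9% of the calls in dilute medium and 22.6% in stationary phase. The second share rests on both arrays, since the balance turned when either stationary-phase replicate was left out. The share in stationary phase was 77.8% with the stationary-phase arrays alone and no dye covariate. With the replicate block as a fixed term the shares were 49.2% in dilute medium and 43.3% in stationary phase. With it as a random term they were 80.9% and 26.2%. With median centring or the scanner software's own signals the lowest share in dilute medium was 77.2%, and the share in stationary phase lay between 24.1% and 25.3%. This argues against the choice of loess over these as the source. Both also leave the median ratio near 0, from -0.013 to 0.042 (log2) in these conditions. An imbalance made or hidden by centring itself would therefore not show, and it stays open. With dilute medium replicate 4, the array with the mutant in Cy5, and 1 of the other arrays, so that the dyes were balanced, the share in dilute medium was 67.9%, 60.9% and 58.4% (57 higher and 27 lower, 81 and 52, 208 and 148, against 100 and 30). In the last of these fits the raised calls grew too and the lowered ones grew more, so unequal dyes stay open as part of the cause. Slide and medium stay confounded, a difference in growth may contribute as well, and whether the shares differ between the conditions was not tested.

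Among the 16 markers and named loci measured on all 4 dilute-medium arrays, Lreu23DRAFT_3227 had 1 array apart from the others, replicate 3 at -1.30 (log2) against -1.54 to -1.53, and chance alone would set apart about 0.8 of 16. Outside the measurements used above, 53.4% of the spike spots, which carry no locus of the strain, were well above background in Cy3 on dilute medium replicate 3 (32.8% in Cy5), against 0% to 4.23% in Cy3 on the other arrays.

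Chance was weighed by turning mutant and wild type on subsets of the arrays. For dilute medium the real assignment gave 130 loci and the highest of the others 1. With 8 splits, of which only the real one gave as many, the share cannot fall under 0.05. For the mean of the conditions 100 splits were run, the real one among them. The real one gave 280 loci and the others at most 140. This argues against chance as the source of the count as a whole, but not for each of the 280 loci. Turning an array also sets the strain difference against itself, which by itself lowers the counts of the other splits.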

How the results depend on the processing

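Fits within each slide, with outlier spots kept and with loci measured on all arrays only were chosen after the data were seen. No named locus changed direction under any alternative run. The causes of the changes below were not tested, except that leaving out arrays or fitting fewer of them changes the degrees of freedom. In the order log phase, stationary phase, dilute medium and mean of conditions, the main counts were 60, 93, 130 and 280, and for the differences, stationary phase minus log phase, dilute medium minus log phase and dilute medium minus stationary phase, they were 0, 2 and 33. With only probes above background the first 4 counts were 58, 88, 127 and 278.

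Scaling between arrays gave 197 loci in log phase (82 higher, 115 lower, against 38 and 22), 165 in stationary phase, and 9, 1 (lower) and 60 for the differences. Array weights gave 502, 297 and 528 for log phase, stationary phase and the mean, and 50, 18 and 122 for the differences. Median centring gave 34 in log phase (27 higher, 7 lower), and 4 (1 higher, 3 lower) and 12 (7 higher, 5 lower) for the differences of dilute medium with log phase and stationary phase. The scanner software's signals gave 0 and 7 (4 higher, 3 lower) for those differences, and so did the deposited value table, 0 and 7. Without the dye covariate the difference of stationary phase and log phase gave 1 locus and that of dilute medium and log phase 1. The median over probes gave 1 for the difference of stationary phase and log phase, and keeping outlier spots gave 3. Within slide 1, log phase gave 409, stationary phase 317 and their difference 87, and within slide 2 dilute medium gave 41. With the arrays of 1 condition alone and no dye covariate, log phase gave 220 and stationary phase 18 (14 higher, 4 lower), and dilute medium 94. With outlier spots kept, which also raised the loci tested from 2092 to 2377, the wild type gave 1224 loci from log phase to stationary phase (543 higher, 681 lower) and 787 from log phase to dilute medium.

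Same-numbered arrays were not taken as pairs: the correlations of their deviations from the condition means were 0.489 for log phase with stationary phase, where the number coincides with dye and slide, and 0.0306 to 0.148 with dilute medium, and the consensus correlation of the random block was 0.523. With the replicate block as a fixed term the counts were 267 (171 higher, 96 lower), 231 (100 and 131), 531 (261 and 270) and 465 (247 and 218). Neither direction thus prevailed clearly in dilute medium or the mean. For the differences the fixed block gave 87 (42 higher, 45 lower), 126 (41 and 85) and 182 (87 and 95). The last of these lost the balance of 25 higher and 8 lower of the main fit. With the block as a random term the mean gave 118 and the differences 17, 4 and 69. For the wild type from log phase to dilute medium the fixed replicate block gave 238, and the fall of Lreu23DRAFT_5167 shrank from -2.71 to -0.94 (adjusted p = 0.208).

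Leaving out each array in turn gave 7 to 111 loci in log phase, 7 to 121 in stationary phase, 42 to 196 in dilute medium and 69 to 348 for the mean, 0 to 1, 0 to 6 and 0 to 43 for the differences, and 571 to 933 and 69 to 555 for the wild type in stationary phase and dilute medium. Of the named loci and ErmC, 286 results of these fits stayed on their side of the threshold, 32 fell below it and 2 passed it. Under the other alternatives 447 stayed, 12 fell below and 31 passed. Not run were the gene lists with either correlation, the luxS transcript and a slide block.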

Other observations

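The test of neighbouring tags and that of the growth stage were fixed before their results were seen; the stretches described first and the growth-stage test on slide 2 alone were chosen after that.

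Many of the lowered loci lay side by side. In the mean of the conditions, 108 of the lowered loci fell into 11 runs of at least 3 consecutive tags, and 40 of the raised loci into 9 runs. The counts of runs differed between the conditions, but this was not tested. Such counts depend on the number of calls in each direction. These were 21 higher and 72 lower in stationary phase and 100 and 30 in dilute medium, and the balance in stationary phase rests on both of its arrays. Stationary phase had 5 lowered runs (48 loci) and 0 raised ones, and dilute medium 0 lowered and 9 raised ones (35 loci). Log phase had 1 lowered run (5 loci) and 3 raised ones (12 loci). The longest run starts at Lreu23DRAFT_3086 and holds 29 loci, with a mean ratio of -0.69 (log2, SD 0.06 over loci) in log phase, -0.75 (SD 0.19) in stationary phase and -0.47 (SD 0.08) in dilute medium. Its means per array lay between -0.76 and -0.61, -1.09 and -0.41, and -1.11 and -0.18 in these conditions, although only 3 of the 29 loci passed in stationary phase and 0 in log phase or dilute medium taken alone. The next run, of 26 loci from Lreu23DRAFT_3975, stood at -1.03 (SD 0.14), -1.33 (SD 0.20) and -0.25 (SD 0.09), and 11, 22 and 0 of its loci passed in log phase, stationary phase and dilute medium. On single dilute-medium arrays its mean ran from -0.84 to 0.12. The longest raised run, 11 loci from Lreu23DRAFT_3805, stood at 0.57 (SD 0.21), 0.20 (SD 0.18) and 0.39 (SD 0.15).

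One hypothesis is that the called loci belong to operons or other units that move together. Of 2101 pairs of consecutive tags, 156 were called in the same direction in the mean of the conditions and 7 in opposite directions. In 100000 random placements of the same calls the mean was 16.9 pairs and the highest 35 (permutation test, one-sided, p = 1e-05, the smallest they can give). This is consistent with shared units, and it does not tell operons from larger elements, since the files do not name the loci.

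A second hypothesis is that the mutant in dilute medium was further towards stationary phase than the wild type beside it. Over 1873 loci with a tag, the effect of the mutation in dilute medium and the change of the wild type from log phase to stationary phase correlated at r = 0.224 (Spearman rho 0.27, and 0.27 again with the mean level held fixed), above all 1872 circular shifts of one list along the tag order, which ran from -0.103 to 0.13. That effect shares its dye covariate with slide 1, and with the slide 2 arrays alone, a fit added later, r was 0.211 (shifts -0.101 to 0.123). Of 76 loci that passed in both, 68 moved the same way, 55 upwards and 13 downwards. Of the others, 6 fell in the wild type and were higher in the mutant, and 2 were the reverse. Raised loci prevailed among all calls in dilute medium (100 higher, 30 lower), while those of the wild type were even (443 and 443). Loci are not independent replicates, and whether 68 of 76 exceeds what unrelated lists would give was not tested. The longest lowered runs leaned against the hypothesis. The 29 loci from Lreu23DRAFT_3086 and the 26 from Lreu23DRAFT_3975 had mean ratios of -0.47 and -0.25 (log2) in dilute medium. In the wild type they rose by 0.74 and 0.36 from log phase to stationary phase. However, 0 of the loci of either run passed in dilute medium, and the array means of the second ran from -0.84 to 0.12. The runs were also picked by the mean of the conditions, so a fall in dilute medium is not shown. The relation is weak and may reflect a shift in growth stage of the mutant, a response to the medium that resembles one, or genes that answer many changes alike, and these data do not separate them.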
